A study of Homo sapiens with 4 samples.

How the data were processed

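RNA from primary human nasal epithelial cells of 2 smoking volunteers was hybridised to 4 one-colour Affymetrix arrays. Per the labels' protocols, cells were expanded in bronchial epithelial growth medium and given either the solvent dimethyl sulfoxide or 14 µM kaempferol for 6 hours. RNA was extracted with TRIzol and labelled as biotinylated cRNA. Each volunteer gave 1 vehicle array and 1 kaempferol array, and groups and volunteer numbers were taken from the sample titles. GEO's description field calls all 4 samples untreated, against the titles of the kaempferol arrays. Their source names and treatment protocols name kaempferol as the titles do, and every difference below rests on that reading. The 2 arrays of a group came from different people, so the spread within a group held differences between people as well as technical variation.

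The deposited table gave 1 normalised value for each of 257430 probesets on each array, used here as log2 intensity. The log base was not stated by the authors. Values between 1.86 and 15.25 made log2 the reading adopted, and the folds printed depend on it. Partek is named in the submitters' processing notes, without a version or a role. Background correction, normalisation between arrays, filters and the annotation used by the authors are not given in the sources used here. Column medians were 8.06 and 8.07 for the vehicle arrays and 8.07 and 8.06 for the kaempferol arrays, so the values had been brought to a common level before deposit. A real change of the total RNA level per cell would not be seen in such values. The number of arrays, 4, limits the precision.

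Gene symbols came from the platform annotation at GEO. Of the probesets, 224320 named 1 gene, 10159 named several genes and were not used, and 22951 were not listed there. XIST and genes of the Y chromosome, 313 probesets, were left out of every step. The log2 values of all probesets naming a gene were averaged (median of 10 probesets per gene), giving 18664 genes. The 30% of genes with the lowest mean over all 4 arrays, 5599 genes with a mean at or below 6.74, were left out as dim, and 13065 genes were tested. Probesets of a gene can respond differently, and the average hides a change limited to some exons. For the named genes, the number of probesets that moved with the gene mean in both volunteers was counted. Symbols in the gene lists were matched to older names through the RefSeq gene table of assembly GRCh38.p14, and 487 of 500 list entries were found. No positions are given, because the genome build of the array annotation is not given in the sources used here.

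Kaempferol and vehicle were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with Benjamini-Hochberg adjustment over the 13065 genes and a threshold of 0.05. All p-values are two-sided. Before the data were examined, the fit without a term for the volunteer was set as the main one, and the fit with the volunteer as a replicate block as its alternative, since no source states a model. The pairing comes from the titles, which give the same volunteer number to 1 array of each group. In a check of it, the difference between the volunteers in the vehicle arrays correlated with that in the kaempferol arrays across genes (Pearson r = 0.69; genes are not independent replicates). Arrays of the same volunteer had the highest correlations, 0.984 and 0.986, against 0.968 to 0.978 for the other pairs of arrays. Every difference below is kaempferol minus vehicle on the log2 scale, given as the mean ± SD of the 2 within-volunteer differences (n = 2). A second count needed no model of the spread. It took genes that changed by at least 1.5-fold (0.58 on the log2 scale) in the same direction in both volunteers, beside those that changed by as much in opposite directions. An exact two-sided test on 2 volunteers cannot give a p below 0.5 for a single gene, so none was run.

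Lists of 18 pathways and 6 cell types were written from textbook knowledge before the data were examined. Each was tested with limma's camera at a preset correlation between genes of 0.01, which compares the list with the other genes, and again with a correlation estimated from the arrays. Each was also tested with fry, which asks whether the list's genes move on balance in one direction (or, in its mixed form, in either direction). P-values were adjusted over the 24 lists. Calls of single members were also adjusted over the list alone.

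The genes named in the text followed a rule fixed with the lists. It took the 10 genes with the largest rise and the 10 with the largest fall among those passing the main fit with the same direction in both volunteers. Where fewer passed, the places went to genes with the largest smaller-of-the-2 within-volunteer differences. Clone and locus names and small RNA genes were passed over. It also took up to 3 members of each list with the largest mean difference among those changed the same way in both volunteers, and always CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, HMOX1 and ALDH3A1. Other genes are marked where they appear.

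Both fits were tested on simulated data, 50 draws of the 13065 genes with the measured volunteer differences. Variances were drawn from the distribution that the blocked fit had estimated. Errors were independent between genes, and a changed gene was shifted equally in both volunteers. In each draw 100 genes changed 1.5-fold and 100 changed 2-fold. The shares that follow hold under these assumptions, which are those of the blocked fit. Without the block, no changed gene was recovered at either fold. With the block, a median of 89% was recovered at 1.5-fold and 100% at 2-fold. The blocked fit leaves 1 residual degree of freedom per gene, and a median of 9.98% of its calls in these draws were false (1.67% to 27.2%), above the nominal level. In 1 draw with independent genes, camera with the preset correlation called a list shifted by 0.3 and no other of the 24. That draw cannot show how many lists it calls falsely where the members of a list vary together. With an estimated correlation camera missed that list (adjusted p = 0.927), though 1 draw does not measure its power with 4 arrays.

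Alternatives were the replicate block, quantile normalisation, median centring, other filters on dim genes, the median in place of the mean of probesets, single probesets, a variance trend with robust moderation, no moderation, other fold limits and leaving out each array in turn. A fit without 1 array had a group of 1 array, which was assumed to vary like the other group. Python 3.11.15 with matplotlib 3.10.9 drew the plots.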

Results

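Gene expression was measured in primary nasal epithelial cells of 2 smoking volunteers after 6 hours with 14 µM kaempferol, a plant flavonol, or with the vehicle dimethyl sulfoxide. There were 2 vehicle arrays and 2 kaempferol arrays, 1 of each per volunteer, going by the titles, sources and treatment protocols of the samples, whereas their description field calls all 4 untreated. After dim genes were left out, 13065 genes were compared. The design asks which genes the flavonol changed in airway cells of smokers.

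With the volunteer as a block, 12 of 28 genes of the response to low oxygen and of glucose breakdown and 4 of 19 cholesterol synthesis genes fell after kaempferol, as did 6 of 25 immediate early and growth factor feedback genes (1 rose) and 5 of 24 inflammatory genes. Of the NRF2 targets of redox defence 5 of 29 rose, of the p53 targets 5 of 24 and of the interferon-stimulated genes 3 of 14 (1 fell). In the fit without the block camera called these 7 lists with a preset correlation (adjusted p = 0.00316 or lower), and none with an estimated correlation (adjusted p = 0.51 or higher). In 1 simulated draw the estimated form missed a list shifted by 0.3, so its lack of calls decides little. Without vehicle replicate 2 the feedback, inflammatory and p53 means were -0.10, 0.018 and 0.12, and camera did not call them. Without kaempferol replicate 1 they were -0.08, 0.034 and 0.10, again uncalled. These fits have 1 lone array and weigh the volunteers unequally, so a difference between volunteers enters the means. Within volunteers 1 and 2 the means were -0.21 and -0.17 (feedback), -0.23 and -0.20 (inflammatory), and 0.24 and 0.21 (p53). Without the block, no single gene passed, but in simulated data that fit recovered no changed gene either. Across genes, the differences within the 2 volunteers had a Pearson r of 0.52 and a Spearman rho of 0.42, computed over genes, which are not independent replicates. By at least 1.5-fold, 131 genes changed the same way in both volunteers, 45 higher and 86 lower, and 1 gene changed in opposite directions by as much. By at least 2-fold, 2 genes were higher in both, 15 were lower in both and 0 went opposite ways.

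In the limma fit without the volunteer as a block, which had been set as the main test, 0 genes were higher and 0 lower at the adjusted threshold. The lowest adjusted p was 0.408, and 1090 genes had an unadjusted p under 0.05 (513 higher, 577 lower). In data simulated under the blocked fit's assumptions, this unblocked fit recovered no changed gene at 1.5-fold or 2-fold. Its lack of calls therefore cannot show that no gene changed. With the volunteer as a replicate block, 266 genes rose and 350 fell, 4.71% of those tested, and all 616 moved in the same direction in both volunteers. The words rose and fell below refer to this blocked fit, and no gene named passed without the block. The blocked counts went to 60 and 98 with the median of probesets, 96 and 132 with no filter on dim genes, 436 and 592 with trend and robust moderation, and 0 with single probesets or without variance moderation. A median of 9.98% of calls were false in data simulated under the blocked fit's own assumptions, and the share among the real calls is not known. All 131 genes changed at least 1.5-fold in both volunteers were among the 616. The blocked fit passes genes whose 2 differences are large and alike. The shared direction of the 616 and the passing of the 131 follow largely from that, and neither is separate evidence of agreement.

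**Figure D1:**
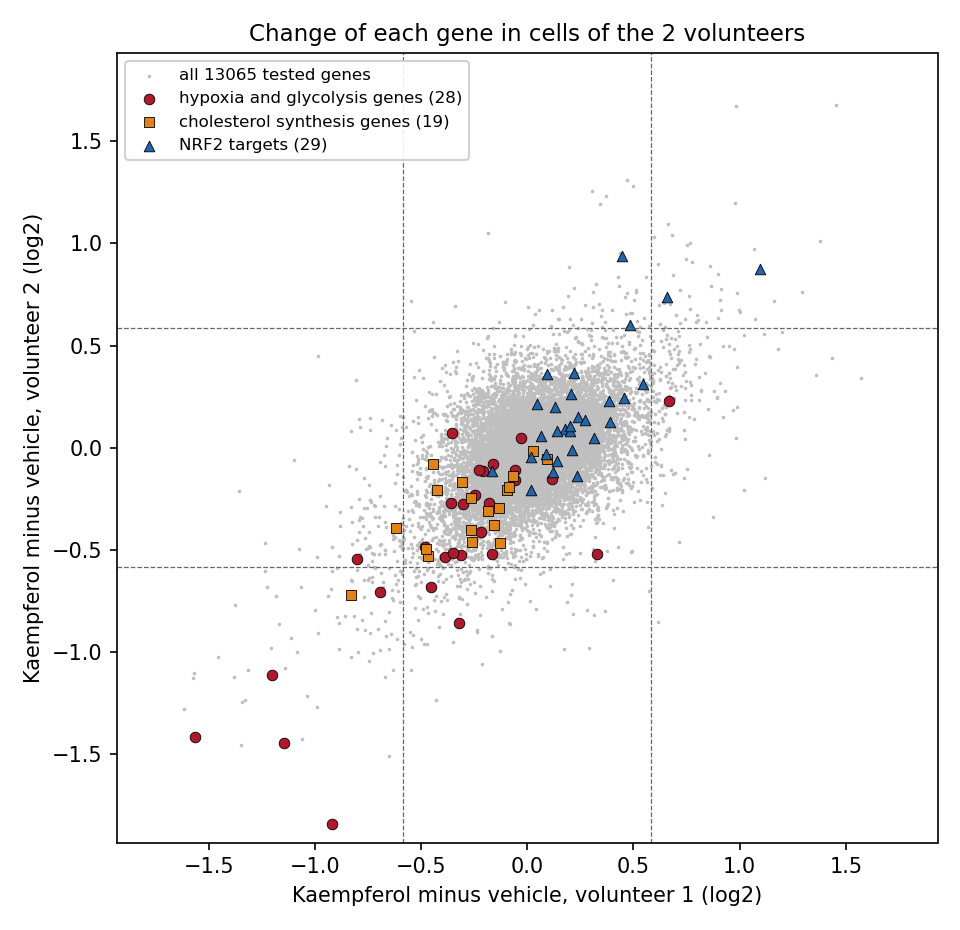
Each point is 1 of 13065 genes, placed by its kaempferol-minus-vehicle difference (log2) in volunteer 1 on the horizontal axis and volunteer 2 on the vertical axis, with dashed lines at 1.5-fold and 3 gene lists in colour. Of the 28 hypoxia and glycolysis genes 23 lie below 0 in both volunteers, as do 17 of the 19 cholesterol synthesis genes, and 21 of the 29 NRF2 targets lie above 0 in both.

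Among the 10 fallers picked by the rule for named genes, the largest mean falls were in EGLN3, an oxygen-sensing prolyl hydroxylase (-1.49 ± 0.11, 2.81-fold, limma adjusted p = 0.000186 with the block and 0.408 without), and CXCL1, a chemokine that attracts neutrophils (-1.45 ± 0.24, 2.73-fold). PRDM1, a transcriptional repressor, fell by 1.40 on the log2 scale. DKK1, a secreted Wnt inhibitor (-1.35 ± 0.31), DUSP4, a MAP kinase phosphatase (-1.33 ± 0.33), and RGS2, a regulator of G protein signalling (-1.29 ± 0.07), fell to a similar extent. PFKFB4, which makes an activator of glycolysis (-1.29 ± 0.21), PLOD2, a collagen lysyl hydroxylase (-1.28 ± 0.07), ANGPTL4, an inhibitor of lipoprotein lipase (-1.25 ± 0.18), and PDK1, the pyruvate dehydrogenase kinase (-1.16 ± 0.06), completed the 10. Their blocked adjusted p ran from 0.000186 to 0.000444, and 10 of the 11 probesets each of RGS2 and ANGPTL4 and all 8 of EGLN3 moved with the gene in both volunteers.

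EGR1, an immediate early transcription factor, had the largest rise (1.57 ± 0.16, 2.96-fold, limma adjusted p = 0.000186 with the block and 0.408 without), with all 5 probesets higher in both volunteers. NEB, which encodes the muscle protein nebulin, rose by 1.33 ± 0.49 at a mean signal of 6.87, near the limit for dim genes at 6.74. The histone gene HIST1H2BJ (1.19 ± 0.26), KLRA1 (1.09 ± 0.16), GDF15, a stress-induced cytokine (1.02 ± 0.07), and SLC7A11, the cystine transporter that supplies glutathione synthesis (0.98 ± 0.16), rose about as much. LRRC69 (0.88 ± 0.02), ZC3H6 (0.87 ± 0.03), CSTF3, a factor of mRNA 3' end processing (0.84 ± 0.09), and the interferon-induced IFITM1 (0.83 ± 0.05) followed. In both vehicle arrays NEB (5.95 and 6.47), HIST1H2BJ (6.18 and 6.66) and KLRA1 (6.70 and 6.56) lay under 6.74. LRRC69 did so in the vehicle array of volunteer 2 (6.57). The first 3 passed the filter on dim genes through their kaempferol values, and the size of their rise is less certain. The blocked adjusted p of these 10 lay between 0.000186 and 0.00213. Probes for near-identical gene copies, such as histone and chemokine genes, can bind each other's RNA.

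**Figure D2:**
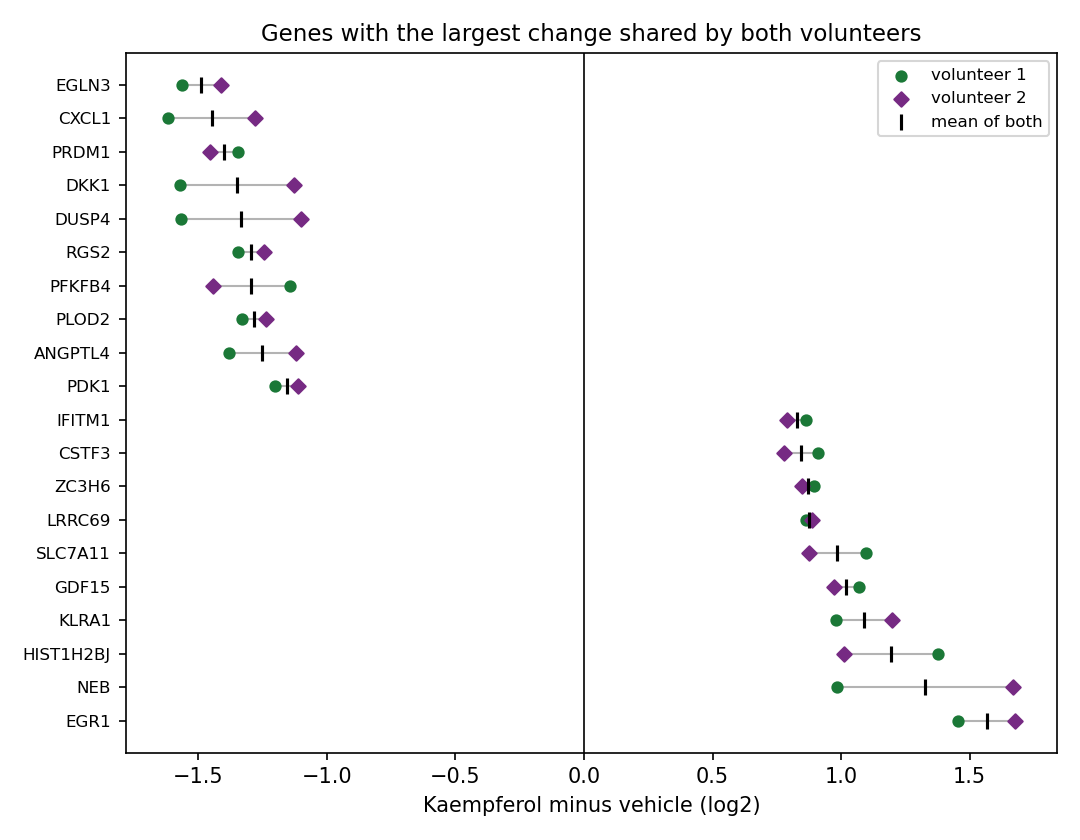
The 20 genes with the largest change shared by both volunteers, with kaempferol minus vehicle (log2) on the horizontal axis, a circle for volunteer 1, a diamond for volunteer 2 and a bar for their mean. EGLN3 at -1.49 and EGR1 at 1.57 are the extremes. By the rule of selection, the 2 volunteers lie on the same side of 0 for each gene.

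Of 24 gene lists, 10 were called by camera with the preset correlation. With an estimated correlation 0 were called, and the lowest adjusted p was 0.51. That estimate rested on 2 residual degrees of freedom. In 1 simulated draw this form missed a list shifted by 0.3 (camera adjusted p = 0.927). A list it did not call may therefore still have changed. Fry, which does not set a list against other genes, called 0 without the block (lowest adjusted p = 0.073) and 0 with it. Its mixed form called NRF2 targets, interferon-stimulated genes and G2/M genes without the block, at an adjusted p of 0.0468 each, and 0 lists with it. For each list called, the adjusted p with an estimated correlation stands beside camera's. Without 1 array, its group's lone array was assumed to vary like the other group, whose spread came from 2 different people. Such a fit also weighs the volunteers unequally, so a difference between them enters the list mean. Calls kept or lost in those fits are therefore weak evidence.

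Hypoxia and glycolysis genes moved farthest, with a mean of -0.42 ± 0.09 over 28 members (camera adjusted p = 8.19e-11, and adjusted p = 0.51 with an estimated correlation). Of these, 12 fell, 0 rose and 16 did not pass. With the block, 16 fell and 1 rose adjusted over the list alone, and 9 passed without it. The largest changes were in EGLN3 and in the paired regulators of glycolytic flux PFKFB3 (-1.38 ± 0.65) and PFKFB4. Others were chosen after their values were seen. PDK1, already named, P4HA1, a collagen prolyl hydroxylase (-0.70 ± 0.01), the first enzyme of glucose use HK2 (-0.57 ± 0.16) and the glucose transporter SLC2A1 (fell by 0.49) were among the 12, while VEGFA (-0.08 ± 0.04), LDHA (-0.17 ± 0.08) and GAPDH (0.01 ± 0.06) did not pass. The mean was -0.27 without vehicle replicate 2 and -0.57 without vehicle replicate 1.

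Cholesterol synthesis genes had a mean of -0.29 ± 0.03 over 19 members, 17 of them lower in both volunteers and none higher in both (camera adjusted p = 2.47e-06, and adjusted p = 0.51 with an estimated correlation). There, 4 fell and 15 did not pass, and adjusted over the list alone 7 fell with the block and 0 without. HMGCS1, which makes the precursor of mevalonate, fell by 0.77 on the log2 scale (1.71-fold, SD 0.08). SQLE, the squalene epoxidase (-0.50 ± 0.05), and STARD4, a sterol carrier (-0.50 ± 0.16), fell as well. Without single arrays the mean lay between -0.38 and -0.19.

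NRF2 targets, genes of antioxidant and glutathione defence, had a mean of 0.22 ± 0.05 over 29 members (camera adjusted p = 2.93e-05, and adjusted p = 0.51 with an estimated correlation). Here 5 rose and 0 fell, and adjusted over the list alone 6 rose with the block and 2 passed without it. SLC7A11 led the list, followed by GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis (0.70 ± 0.06), and TXNRD1, thioredoxin reductase (0.69 ± 0.35). Other well-known targets did not pass: NQO1 was at 0.03 ± 0.09 and HMOX1 at -0.14 ± 0.04. The sign of NQO1, which the AHR list also holds, differed between the volunteers.

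Targets of the aryl hydrocarbon receptor (AHR), the sensor of smoke hydrocarbons and some flavonoids, showed no common direction. Over 14 members the mean was 0.03 ± 0.14 while the median was -0.05 and camera's direction was down (adjusted p = 0.473, and adjusted p = 0.696 with an estimated correlation). CYP1B1 (0.96 ± 0.87) and UGT1A6 (0.94 ± 0.70) rose, unevenly: CYP1B1 by 1.57 in volunteer 1 and 0.34 in volunteer 2, UGT1A6 by 1.43 and 0.44. UGT1A6 rested on 1 probeset. Adjusted over the list alone, 2 rose and 2 fell with the block and 0 passed without. CYP1A1, the best-known target, was too dim to test and had differences of 0.42 and -0.67. AHRR (0.02 ± 0.41), TIPARP (-0.36 ± 0.05), LRAT (-0.47 ± 0.55) and ALDH3A1 (-0.0036 ± 0.13, with opposite signs in the 2 volunteers) did not pass. The list mean was 0.15 without kaempferol replicate 2, -0.09 without kaempferol replicate 1, -0.03 with the median of probesets and -0.13 without its 2 largest members, uncalled in each.

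Among immediate early and ERK feedback genes, 6 of 25 fell and 1 rose, with a mean of -0.19 ± 0.03 (camera adjusted p = 0.00298, and adjusted p = 0.51 with an estimated correlation). The count adjusted over the list alone was 8 fallen and 1 risen with the block, and 4 passed without it. EGR1 rose, and DUSP4 fell, as did KLF6 (-0.81 ± 0.17), a zinc finger transcription factor. Chosen after their values were seen, the ERK pathway inhibitors DUSP6 (-0.54 ± 0.13), SPRY4 (-0.45 ± 0.15) and SPRED1 (1.54-fold) fell too. Their relatives DUSP5 (0.18 ± 0.18), SPRY2 (0.03 ± 0.33) and SPRED2 (-0.17 ± 0.24) did not pass, nor did FOS (0.03 ± 0.28) and JUN (-0.08 ± 0.27). Camera's call was lost without vehicle replicate 2 (mean -0.10, adjusted p = 0.103) and without kaempferol replicate 1 (mean -0.08, adjusted p = 0.121), and the mean was -0.30 without kaempferol replicate 2.

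NF-kB and inflammatory genes had a mean of -0.22 ± 0.02 over 24 members, of which 5 fell and 0 rose (camera adjusted p = 0.00298, and adjusted p = 0.696 with an estimated correlation). Beside CXCL1, PTGS2, the inducible cyclooxygenase (-1.02 ± 0.22), and TNFAIP3, a feedback inhibitor of NF-kB (-0.77 ± 0.05), fell. With the block, 8 fell and 2 rose adjusted over the list alone, and 1 passed without it. Chosen after their values were seen, IL8 (-0.62 ± 0.15) and CXCL3 (-0.45 ± 0.09) fell, while IL1A (0.33 ± 0.11) and IL1B (0.29 ± 0.14) did not pass. The list's mean changed sign without vehicle replicate 2 (0.018, adjusted p = 0.388) and without kaempferol replicate 1 (0.034, adjusted p = 0.687), fits in which the volunteers are no longer balanced. It was -0.45 without vehicle replicate 1 and -0.47 without kaempferol replicate 2.

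The p53 targets had a mean of 0.23 ± 0.02 over 24 members, with 5 risen and 0 fallen (camera adjusted p = 0.00316, and adjusted p = 0.562 with an estimated correlation). GDF15, the DNA repair factor XPC (0.76 ± 0.20) and the antiproliferative BTG2 (0.67 ± 0.08) led. The cell cycle inhibitor CDKN1A, chosen after its values were seen, rose by 0.46 ± 0.02. Adjusted over the list alone, 10 rose and 1 fell with the block and 0 passed without. The call was lost without vehicle replicate 2 (mean 0.12, adjusted p = 0.247) and without kaempferol replicate 1 (mean 0.10, adjusted p = 0.121), and the mean was 0.35 without kaempferol replicate 2.

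Interferon-stimulated genes had a mean of 0.23 ± 0.09 over 14 members (camera adjusted p = 0.00193, and adjusted p = 0.51 with an estimated correlation). Of this list 24 genes were on the array, and the rest were left out as dim. The antiviral genes OAS2 (0.83 ± 0.24), IFI6 (0.61 ± 0.10) and MX1 (0.56 ± 0.26) rose. For MX1, 8 of 17 probesets moved with the gene in both volunteers. The RNA sensor DDX58, chosen after its values were seen, fell (-0.53 ± 0.29), and 10 members did not pass. The blocked count adjusted over the list alone was 5 risen and 1 fallen, and 1 passed without the block.

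ATF4 and integrated stress response genes had a mean of 0.19 ± 0.10 over 22 members (camera adjusted p = 0.000835, and adjusted p = 0.51 with an estimated correlation). SLC7A11, also an NRF2 target, and AARS, the alanyl-tRNA synthetase (0.47 ± 0.05), rose, and SESN2 (0.35 ± 0.02) did not pass. Adjusted over the list alone, 3 rose with the block and 0 passed without. This call was lost without vehicle replicate 1 (mean 0.10, adjusted p = 0.0939). Unfolded protein response genes had a mean of 0.18 ± 0.12 over 19 members (camera adjusted p = 0.00102, and adjusted p = 0.61 with an estimated correlation). The chaperone partner DNAJB9 rose (0.84 ± 0.40), MANF (0.37 ± 0.01) and HSPA5 (0.24 ± 0.08) did not pass, and adjusted over the list alone 2 rose with the block and 0 passed without.

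G2/M genes had a mean of 0.15 ± 0.04 over 12 members (camera adjusted p = 0.0312, and adjusted p = 0.51 with an estimated correlation). The list held 29 genes on the array, and the rest were left out as dim. CCNA2, cyclin A2, rose (0.61 ± 0.16), while the mitotic kinases PLK1 (0.34 ± 0.09) and AURKA (0.32 ± 0.09) did not pass. Adjusted over the list alone, 3 rose with the block and 1 passed without it. The call was lost without vehicle replicate 1 (mean 0.12, adjusted p = 0.111), without kaempferol replicate 2 (mean 0.09, adjusted p = 0.494), with the median of probesets (adjusted p = 0.0904) and without its 2 largest members (adjusted p = 0.278).

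**Figure D3:**
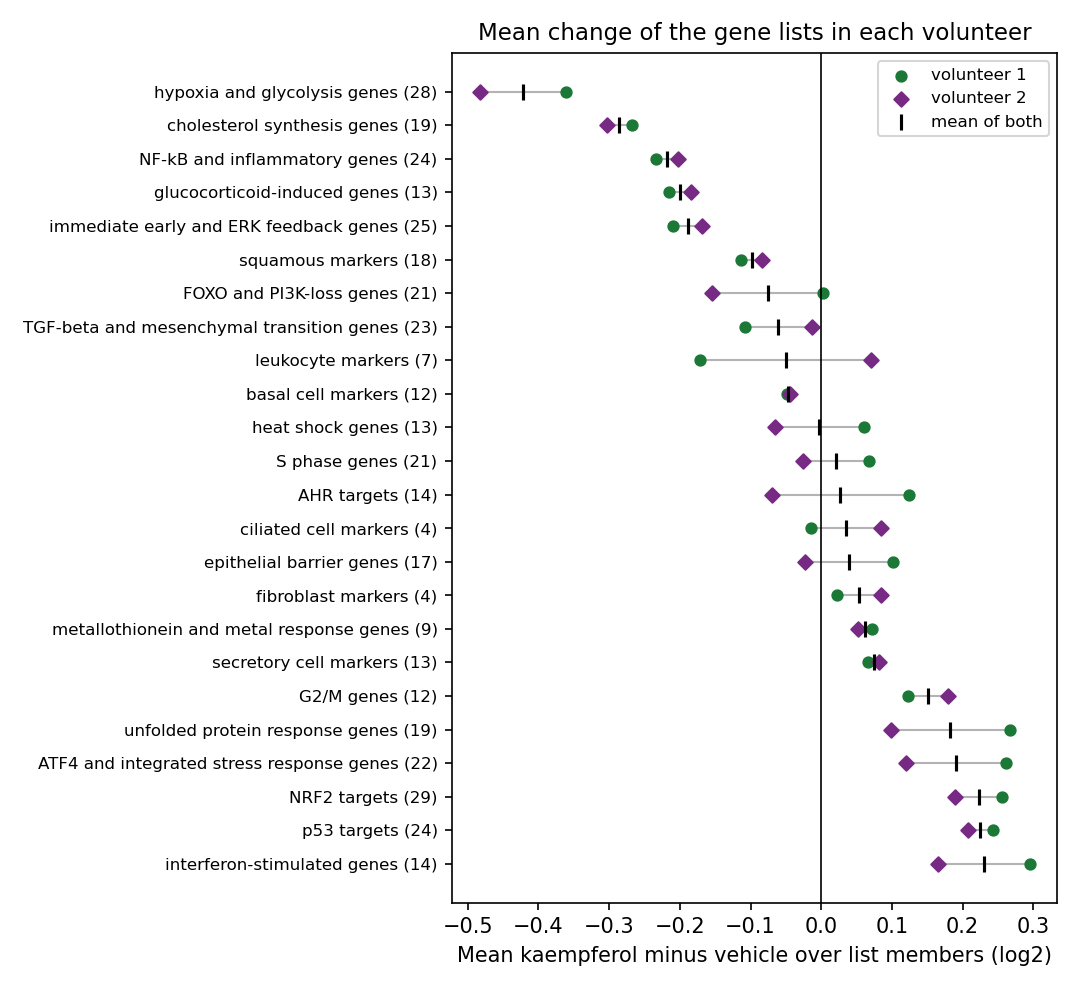
Mean kaempferol-minus-vehicle difference (log2) over the tested members of each of the 24 lists, with the number of members in brackets, a circle for volunteer 1, a diamond for volunteer 2 and a bar for their mean. The hypoxia and glycolysis list lies lowest, at -0.36 and -0.48, and the interferon list highest by its mean, at 0.30 and 0.17.

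Camera did not call the other 8 pathway lists, AHR targets among them, in the fit without the block. In those other than the AHR targets, and in the cell type lists, the blocked counts adjusted over the list alone equalled those over all genes. Glucocorticoid-induced genes came closest, with a mean of -0.20 ± 0.02 over 13 members (adjusted p = 0.0513, and adjusted p = 0.51 with an estimated correlation). It was called with the block (adjusted p = 0.0396), with no filter on dim genes (adjusted p = 0.0199) and with the median of probesets (adjusted p = 0.0419). The fall lay in ANGPTL4, ERRFI1, an EGF receptor inhibitor (-0.76 ± 0.22), and the phosphatase DUSP1 (-0.58 ± 0.12), whereas the list's median was -0.02. Without the block, 2 of its genes passed when adjusted over the list alone. Among TGF-beta and mesenchymal transition genes (mean -0.06 ± 0.07, adjusted p = 0.524, and adjusted p = 0.907 with an estimated correlation), the activin subunit INHBA (-0.92 ± 0.45) and THBS1 (-0.62 ± 0.47) fell and the matrix protein gene CYR61 rose (0.62 ± 0.01), as did ID3 (0.44 ± 0.13), chosen after its values were seen. At the preset correlation that list was called without kaempferol replicate 2 (mean -0.30, adjusted p = 0.00242), but its mean was 0.18 without kaempferol replicate 1 and 0.13 without vehicle replicate 2. Of the FOXO and PI3K-loss genes (mean -0.08 ± 0.11, adjusted p = 0.41), CCNG2 (-0.64 ± 0.21), CITED2 (-0.48 ± 0.23) and BNIP3 (-0.59 ± 0.38), which the hypoxia list also holds, fell.

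S phase genes had a mean of 0.02 ± 0.07 (adjusted p = 0.922), and CCNE1 (0.29 ± 0.24), UHRF1 (-0.29 ± 0.18) and PCNA (0.26 ± 0.23) did not pass. Their list mean was 0.14 without kaempferol replicate 2 and -0.09 without kaempferol replicate 1. Heat shock genes had a mean of -0.0027 ± 0.09 (adjusted p = 0.733), with DNAJB1 at 0.32 ± 0.12, HSPH1 at -0.17 ± 0.09 and HSP90AB1 at -0.16 ± 0.10, none passing. The metallothionein list (mean 0.06 ± 0.01, adjusted p = 0.473) had no member past the threshold. Its mean was 0.005 without vehicle replicate 1 and 0.12 without vehicle replicate 2, fits that weigh the volunteers unequally. With the median of probesets it was 0.14, so the small SD of the 2 volunteers does not cover the choice of probeset summary. MT1G was at 0.26 ± 0.02, MT1X at 0.17 ± 0.15 and MT1H at 0.10 ± 0.12, and these copies are alike in sequence. Epithelial barrier genes had a mean of 0.04 ± 0.09 (adjusted p = 0.703). CLDN4 (0.35 ± 0.07), CDH3 (0.18 ± 0.03) and DSC2 (-0.14 ± 0.09) did not pass.

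No cell type list was called in the fit on all 4 arrays, with or without the block. Basal cell markers had a mean of -0.05 (0 of 12 rose and 1 fell), the faller being TP63, the basal cell transcription factor (-0.48 ± 0.16). KRT15 (0.36 ± 0.31) and LAMB3 (-0.26 ± 0.08) did not pass. Of 18 squamous markers (mean -0.10 ± 0.02, adjusted p = 0.195, and adjusted p = 0.696 with an estimated correlation), CNFN, cornifelin, fell (-0.70 ± 0.07), and IVL (-0.35 ± 0.37) and SCEL (-0.27 ± 0.01) did not pass. They were called at the preset correlation without kaempferol replicate 2 (mean -0.18, adjusted p = 0.0164), but their mean was -0.02 without kaempferol replicate 1 (adjusted p = 0.89) and -0.04 without vehicle replicate 2 (adjusted p = 0.609). Secretory cell markers had a mean of 0.07 ± 0.01 over 13 members; the mucin gene MUC5B rose on 1 probeset (0.64 ± 0.19), and AGR2 (0.23 ± 0.02) and PLUNC (0.22 ± 0.02) did not pass. Ciliated cell markers (mean 0.04 ± 0.07) and fibroblast markers (mean 0.05 ± 0.04) had 4 members each above the limit for dim genes, and leukocyte markers (mean -0.05 ± 0.17) had 7. None of their members passed, among them FOXJ1 (-0.07 ± 0.01), CCDC40 (0.20 ± 0.05), COL1A1 (0.14 ± 0.06), COL3A1 (0.13) and COL1A2 (-0.06 ± 0.02). Leaving out 1 array turned the sign of the heat shock, epithelial barrier, basal, secretory, ciliated, fibroblast and leukocyte means, with no call. No batch is named in the labels, so a handling difference between vehicle and kaempferol dishes cannot be told apart from the treatment.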

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

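Probesets that the gene table does not list stood outside every comparison of genes, and some of them differed between kaempferol and vehicle arrays in both volunteers. Of 22951 such probesets, 86 were at least 2-fold higher and 100 at least 2-fold lower after kaempferol in both volunteers, and 131 moved by as much in opposite directions. Their differences in the 2 volunteers had a Pearson r of 0.095 across probesets, which are not independent replicates. Among the 224007 probesets that name 1 gene, the counts were 1443 higher, 1614 lower and 2050 opposite, with an r of 0.11. Opposite changes were fewer than shared ones in both sets, though closer to them in number than among the averages per gene, where 2 genes were 2-fold higher and 15 lower in both and 0 went opposite ways. Probeset 8119426 was higher by 2.95 on the log2 scale (3.20 and 2.70 in the 2 volunteers), and 8171459 was higher by 2.40. Probeset 8054558 differed by -3.22 (-3.16 and -3.28), and 7916673 by -2.58. These 4 were chosen after their values were seen, lay between 2.26 and 7.02 on all arrays, and were not tested. The dimmer group was vehicle for 8119426 and 8171459 and kaempferol for 8054558 and 7916673. Its values, 2.26 to 4.19, lay far under the lower quartile of each array (6.25 or higher). Signals that low may be background, so the sizes of these differences are uncertain. No explanation was tested for them.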

How the results depend on the processing

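The combinations of the replicate block with another choice, the stricter threshold, the estimated correlations, fry and the lists without their 2 largest members were chosen after seeing the data. Without the block, 0 genes were called in either direction under all other settings and without any single array, with 623 to 10391 features at an unadjusted p under 0.05. The main fit without the block recovered no changed gene in simulated data, so these counts do not show an absence of change. Pairing by volunteer gave 266 higher and 350 lower genes in limma. With the block, quantile normalisation gave 239 higher and 300 lower, and median centring 181 and 328. No filter on dim genes gave 96 and 132, leaving out the lowest 50% gave 227 and 382, and the median of probesets gave 60 and 98. A variance trend with robust moderation gave 436 and 592, and an adjusted p under 0.01 gave 61 and 104. Single probesets and no moderation gave 0 and 0, with 15556 and 1013 features at an unadjusted p under 0.05. Of the 616 blocked calls, 537 were shared with quantile normalisation, 509 with median centring, 138 with the median of probesets and 603 with trend and robust moderation. The cause was not tested. A blocked fit without 1 array leaves no residual degrees of freedom.

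The 131 genes changed at least 1.5-fold the same way became 197 with the median of probesets (78 higher, 119 lower, 11 opposite). With a limit of 0.32 on the log2 scale they were 676, and with a limit of 1 they were 17. Other settings gave 96 to 183. Of the 24 lists, camera called 10, or 11 with the block, 7 to 11 without 1 array and 9 without the 2 largest members of each. With an estimated correlation it called 0, and 0 with the block added, though the estimated form also missed the shifted list in the simulated draw. Fry called 0 and 0. Leaving out 1 array moved the NF-kB list mean between -0.47 and 0.034; it was 0.018 without vehicle replicate 2 and 0.034 without kaempferol replicate 1. Those fits weigh the volunteers unequally between groups. A lone array was assumed there to vary like the other group. The block changed the call of 1 list (glucocorticoid-induced genes), which no filter on dim genes (adjusted p = 0.0199) and the median of probesets (adjusted p = 0.0419) also brought past the threshold, and it brought 50 of 84 tested named genes past the threshold. Named genes kept their direction without single arrays in 324 fits and changed sign, uncalled, in 12. With the median of probesets 6 of them changed sign (PCNA, DSC2, SCEL, PLUNC, FOXJ1 and COL1A2) and with quantile normalisation 1 did (ALDH3A1), all uncalled. Dim genes, with a mean at or below 6.74, were not tested.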

Other observations

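The gene families, other than the HIF targets outside the list, and all genes named in this part were picked after their values were seen. The tests against random lists, of short-lived transcripts, of S phase and of small nucleolar RNA genes were also chosen after the results were seen. The tests of scaling and of the HIF targets outside the list were set before their values were computed, though after the lists' changes were known. The conditions that left scaling, short-lived transcripts and S phase undecided were added after those values were seen. Rose and fell again refer to the limma fit with the volunteer as a replicate block, and none of these genes passed without it.

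Several regulators not yet described changed in both volunteers. Genes of the KLF family, zinc finger transcription factors that take part in epithelial differentiation, had a mean of -0.37 ± 0.06 over 15 members, of which 5 fell, KLF6 among them, and 0 rose. KLF3 fell by 0.87, and KLF11 (-0.85 ± 0.06) and KLF4 (-0.67 ± 0.04) fell as well. The family mean stayed between -0.40 and -0.36 under quantile normalisation, median centring and the median of probesets. SLC38A2, an amino acid transporter (-1.20 ± 0.16), the activin antagonist FST (-1.24 ± 0.30) and RASA2, a Ras GTPase-activating protein (-1.09 ± 0.16), fell more than 2-fold. ETS1, a transcription factor (-0.94 ± 0.07), and BACH1, a repressor of antioxidant genes (-0.83 ± 0.15), fell, as did the collagenase MMP1 (-0.86 ± 0.05) and the keratin KRT78 (-0.82 ± 0.01).

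The fall of the hypoxia and glycolysis list (mean -0.42 ± 0.09) lay below the lowest mean of 10000 random lists matched on signal, -0.20, which argues against a trend with brightness. Quantile normalisation left the mean at -0.41, but it moved no list or family mean by more than 0.012, so it decides nothing about scaling between the arrays. First-wave immediate early genes had a median of -0.0018, 0.31 above the list's (SE of that difference 0.13, over genes). Their SD of 0.57 over 9 genes was widened by EGR1 at 1.57, while the others lay between MYC at -0.40 and FOSB at 0.10. As a set they did not fall as the list did. They were few and went both ways (2 higher and 3 lower in both volunteers), so a general loss of short-lived transcripts stays open. Other targets of the hypoxia-inducible factor HIF, 29 genes absent from the list, had a mean of -0.34 ± 0.12, with 25 lower in both volunteers, 10 fallen (STC1 at -1.08, KDM3A at -0.82) and 0 risen, consistent with the hypothesis that HIF targets at large fell after kaempferol. Differences in cell density, oxygen or handling between dishes stay open, as they cannot be told apart from the treatment here.

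Histone genes were higher, with a mean of 0.40 ± 0.09 over 35 genes, 14 risen and 0 fallen (HIST1H4D at 0.94, HIST2H2BE at 0.79), and the mean lay between 0.38 and 0.48 under the 2 scalings and the median of probesets. The highest mean of 10000 lists matched on signal was 0.13, which argues against a brightness trend. The S phase list showed no rise shared by both volunteers. Its mean was 0.021 (0.067 and -0.025 in volunteers 1 and 2), against 0.467 and 0.340 for the histone genes. Its members went both ways (7 higher and 8 lower in both volunteers, SD 0.16). The list mean was 0.14 without kaempferol replicate 2 and -0.09 without kaempferol replicate 1, fits that weigh the volunteers unequally. The SE of the mean over members was 0.036, though genes are not independent replicates. In neither volunteer did the S phase list rise as much as the histone genes. A small rise was not excluded, so more cells in S phase stay open. Small nucleolar RNA genes, whose RNA lacks poly(A) tails as many but not all histone mRNAs do, had a mean of 0.126, higher than 0. It lay below the histone genes by more than the error of that difference (SE 0.061 over genes, which are not independent replicates). The gap was wider in volunteer 1 (0.055 against 0.467) than in volunteer 2 (0.197 against 0.340). Greater recovery of such RNA could therefore account for part of the rise and stays open, as does binding of near-identical histone copies to each other's probes, which would make the 14 calls fewer independent events.

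Genes named ZNF, most of them encoding zinc finger proteins, had a mean of 0.13 ± 0.06 over 414 genes, of which 222 were higher and 76 lower in both volunteers, 48 rose and 6 fell. The highest mean of 10000 lists matched on signal was 0.049, which argues against a brightness trend. After quantile normalisation the mean lay 0.114 above the median of all tested genes, but that step moved too little to decide about scaling between the arrays. Scaling could therefore still be part of it, although the mean was higher than 0 in both volunteers under each scaling tried. No biological explanation was tested for it beyond the treatment itself.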
